A study of Arabidopsis thaliana with 21 samples.

How the data were processed

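Whole etiolated seedlings of Arabidopsis thaliana (ecotype Col-0, wild type or pif3 mutant) were profiled on 1-colour Affymetrix arrays, 1 biotin-labelled sample per array. Per the labels' protocols, seeds were sterilized, plated without sucrose, kept cold at 4 °C for 4 days, given 3 h of white light and grown at 21 °C in darkness for 4 days. Total RNA was column-purified and 5 ug was labelled by the manufacturer's standard procedure, per the labels' protocols. The labels give 7 groups of 3 biological replicates. WT_D0 and pif3_D0 were collected after 4 days of darkness, WT_D1 and pif3_D1 after 1 h more and WT_D18 after 18 h more of darkness. WT_R1 and WT_R18 were moved to continuous red light for 1 h and 18 h.

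The deposited values are intensities on a linear scale, 1 per probe set and array. The software that summarised the probes and any scaling by the authors are not given in the sources used here. Between 9.78% and 12.1% of an array's deposited intensities lay below 0. The arrays had no common scale: their medians ran from 36.13 to 102.9 and their means from 151.9 to 381.2. Detection calls were not used here, so no probe set was called present or absent. The number of arrays limits the precision, and each array gives 1 value per probe set. Within a group the log2 values of different arrays correlated at r of 0.977 to 0.992 across probe sets, so no 2 arrays of a group held identical values.

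Of 22810 probe sets, 64 controls were set aside and 22746 were tested. Arrays were quantile normalized on the linear scale, values below 0 were set to 0, an offset of 16 was added and log2 was taken. The plan made before the data were examined took the deposited scale as it stood and listed quantile normalization of the log2 values as an alternative. The lack of a common scale and the values below 0 led to the change, with the normalization moved before the log step, and the unscaled values became an alternative chosen after seeing the data. A log2 fold change is therefore on the log2(value + 16) scale and understates the change of dim probe sets. Group means and SDs are given as quantile-normalized intensities before the floor, so some lie below 0. A log2 change against such a group is on the offset scale and its size rests on the offset, and no fold of the intensities is given.

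limma 3.58.1 in R 4.3.3 fitted 7 group means over all 21 arrays, which share 1 estimate of the spread per probe set. Contrasts were tested with moderated statistics (lmFit and eBayes) and Benjamini-Hochberg adjustment over the 22746 probe sets, and a probe set was called at an adjusted p under 0.05. The comparisons were red light against darkness at 1 h and at 18 h, pif3 against wild type at D0, at D1 and as the mean of both, the dark times against each other in each genotype, and the 2 differences of differences. All p-values in the text are limma's, adjusted, two-sided unless said otherwise.

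Probe sets were named through the platform's annotation and a gene table of assembly TAIR10.1, used for names only. Of the probe sets, 13513 had 1 gene, 503 had several and were left unnamed, and 8730 tested ones were not listed and stay unnamed here. The named probe sets gave 13356 genes, each represented by its brightest probe set, and 1535 had a symbol other than the locus. Where a gene had several probe sets, the call differed between them for 14 of 146 genes at red 1 h, 50 at red 18 h and 5 for the pif3 mean, with no opposite calls. No probe set of the PIF3 gene is named here, so the mutation could not be checked in the arrays and PIF3 was not analysed here. No coordinates are printed because the array values name no genome build.

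Before the data were examined, 26 gene lists with 427 entries were fixed, of which 66 entries (in a named probe set of their own) were measured. The 9 lists with at least 3 measured members were tested. Measured were 3 of 21 antenna entries (all LHCB4 genes), 5 of 26 photosystem, 3 of 17 Calvin cycle and 8 of 28 tetrapyrrole entries. The others had 3 of 18 shade, 8 of 36 auxin, 9 of 24 expansin, 3 of 17 gibberellin and 6 of 21 flavonoid entries. A list result below speaks for these members only. A further 34 families, defined by gene names, were fixed after the probe annotation was read and before any expression comparison. Sets were tested with camera (preset correlation of 0.01), again with an estimated correlation, and with fry, adjusted over the lists or over the families within each comparison. Named genes followed a rule fixed before the data were examined. For red 1 h, red 18 h and the pif3 mean these were the 8 largest increases and 8 largest decreases among called genes whose groups did not overlap (at each time for the pif3 mean). Other comparisons took 5 and 5, and each described list gave up to 4 members past the test, or the member with the smallest p. Genes outside the rule are said to be so where they appear.

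The steps were tested on simulated data with the real means, spreads and array scales, with 200 changed probe sets in each of 10 draws over 22746 probe sets. The changed probe sets were drawn from the brighter ones only, so recovery among dim probe sets was not tested. For red 1 h, 45.2% of log2 changes of 0.5 were recovered, 88.7% of those of 1 and 99.2% of those of 2. For the pif3 mean these shares were 71%, 96.3% and 99.4%. The share of false calls was 7.84% for red 1 h and 6.31% for the pif3 mean, somewhat above the nominal level. camera with the preset correlation found a list of bright probe sets, all raised together with independent noise, in each draw. Lists as small as most of those tested here, or with correlated members, were not simulated. Alternatives were median scaling, no scaling, a filter on dim probe sets, a variance trend, fits of the compared groups alone, 1 probe set per gene, other offsets, a replicate block, a control taken before the light, the omission of each array, and settings that use the signal of the 25S rRNA control probe set. The last kind was chosen after that signal had been seen to differ between arrays.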

Results

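The 21 arrays measured transcript levels in dark-grown Arabidopsis seedlings, 3 biological replicates in each of 7 groups. The groups follow wild type in darkness (WT_D0, WT_D1, WT_D18), wild type after 1 h or 18 h of red light (WT_R1, WT_R18) and the pif3 mutant in darkness (pif3_D0, pif3_D1). PIF3 is a basic helix-loop-helix transcription factor that binds phytochrome, the red light receptor. The first principal component of the normalized values held 41.2% of the variance and the second 12.3%. On the second component WT_R1 replicate 2 (43.49) and WT_D18 replicate 2 (35.74) lay highest. Technical signals differed between arrays. The 3' to 5' ratio of the GAPDH control ran from 1.3 to 1.94, highest in pif3_D0 replicate 3, which also had the lowest deposited median. The 25S rRNA control probe set lay at 128 to 466 intensity units in the 3 WT_R1 arrays and at 4289 to 5410 in the 6 pif3 arrays. In wild-type darkness it lay at 624 in WT_D0 replicate 1, 689 in WT_D1 replicate 2 and 365 in WT_D18 replicate 1, against 2043 to 4927 in the other 6 arrays. In the 3 WT_R18 arrays it lay at 2650 to 3423. Signals above 2000 units count as high here, and WT_D18 replicate 3 lay near that cut, at 2043.

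**Figure D1:**
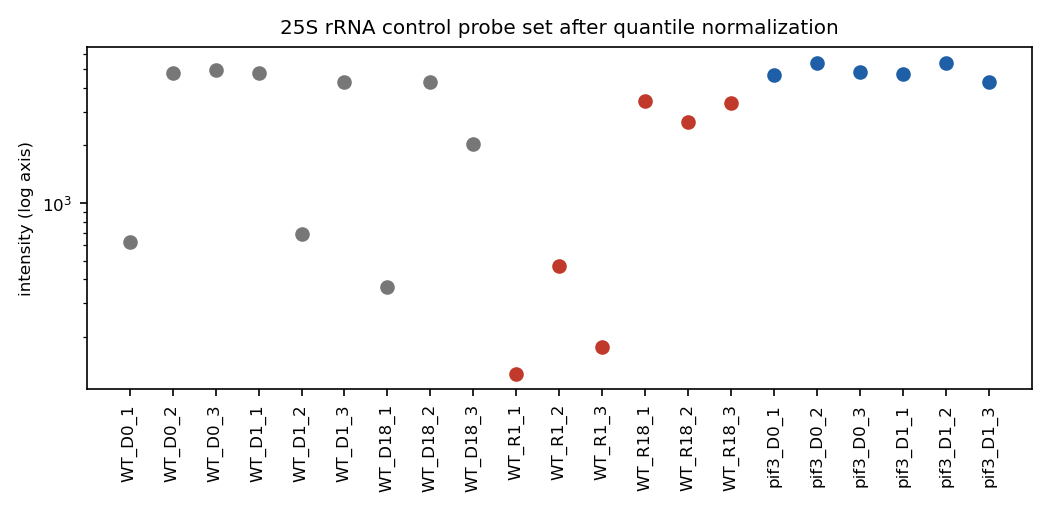
Quantile-normalized intensity of the 25S rRNA control probe set on a log axis, 1 point per array, with dark wild type in grey, red light in red and pif3 in blue. The 3 WT_R1 arrays and 1 array of each dark wild-type group lie at or below 689 and every pif3 array lies at or above 4289.

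After 1 h of red light, wild-type seedlings changed a limited set of genes. The measured shade and PIF target genes were lower, and the antenna list, of LHCB4 genes only, was higher. UGT78D2, a flavonoid 3-O-glucosyltransferase, rose from 34.71 ± 1.61 to 292.9 ± 9.46 intensity units (SD, n = 3 each), a log2 change of 2.61 (SE 0.14). The clock gene GI rose by 1.58 on the log2 scale, and HYH, a bZIP factor closely related to HY5, rose from near background, at 7.018 units, to 104.4. IAA29, an auxin-inducible Aux/IAA gene, fell by 2.09 and EXO, a gene linked to brassinosteroid-promoted growth, fell by 1.71. In all, 1124 of 22746 probe sets were called, 633 higher and 491 lower, and 305 of them changed at least 2-fold.

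The largest increases at 1 h among named genes, with the offset used here, were AT1G64500 (log2 change 3.24, adjusted p = 2e-08), which went from 53.78 ± 7.29 to 642.7 ± 14.4 units, AT5G58750 (3.11), AT3G02910 (2.90), SNZ (2.87), UGT78D2, THI2.2 (2.56), AT5G15950 (2.45) and HYH (2.40). SNZ encodes an AP2-type transcription factor and THI2.2 a thionin. SNZ and THI2.2 had mean intensities below 0 in darkness, at -5.848 and -11.2, AT5G58750 had 0.1087, and they had 120, 85.06 and 134.6 units after 1 h. These 3 and HYH were the 4 of the 16 ranked genes with a group mean under the offset, so that the size and rank of their changes rest on it: over all settings tried they ran from 1.46 to 5.81 for SNZ, 1.17 to 6.29 for THI2.2, 1.60 to 6.04 for AT5G58750 and 1.24 to 3.96 for HYH. The largest decreases were AT5G02580, which fell by 2.43 on the log2 scale from 642.8 ± 76.9 to 107.6 ± 25.1 units, followed by IAA29, AT4G36010 (-1.94), AT4G35720 (-1.93), AT5G57760 (-1.76), AT4G16670 (-1.74), EXO and AT1G77200 (-1.63), which was at 16.83 units after red light and ran from -2.35 to -0.87. EXO remained an abundant transcript, at 3668 ± 351 units in darkness and 1107 ± 99.7 after red light. The adjusted p of these 16 genes ran from 3.3e-09 for AT3G02910 to 0.0011 for AT5G57760.

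Among the gene lists, shade and PIF target genes fell at 1 h: all 3 measured members were lower, and 3 were lower when adjusted over the list alone (camera adjusted p = 4.3e-09). FHL, which acts in phytochrome A nuclear import, fell by 0.84 and HAT2, a homeodomain-leucine zipper gene, fell by 0.67, beside IAA29. The auxin response list was lower (adjusted p = 7.9e-05), with 4 of 8 members called lower over all genes and 4 when adjusted over the list alone. IAA29 and HAT2 belong to both lists. Without them the auxin response list was not called (median -0.25, camera adjusted p = 0.087, and 0.13 with an estimated correlation), with 2 of its other 6 members called: GH3.3, an auxin-conjugating enzyme, fell by 1.00 and IAA20 fell by 0.93. The antenna proteins were higher (adjusted p = 0.0013), with 2 of 3 members called and 2 adjusted over the list alone: LHCB4.3 rose by 0.53 and LHCB4.2 by 0.42. LHCB4.1 was at 0.04 (limma adjusted p = 0.94). The photosystem and electron transport subunits were higher with the preset correlation (adjusted p = 0.00012), and the adjusted p was 0.056 with an estimated correlation. PSBY (0.68) and PSBW (0.50) were the 2 of its 5 members called, with 4 higher when adjusted over the list alone. The flavonoid and phenylpropanoid list was higher (adjusted p = 0.011) through UGT78D2, the only 1 of its 6 members called at either adjustment, while the list's median change was 0.05. With any 1 of the 6 arrays left out, GH3.3 and LHCB4.3 lost their call over all genes in 4 fits and PSBY and PSBW in 3. With the 25S rRNA signal as a covariate the adjusted p was 0.29 for GH3.3, 0.2 for LHCB4.3, 0.1 for LHCB4.2, 0.35 for PSBY and 0.13 for PSBW.

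The other lists were not called at 1 h. The adjusted p was 0.078 for the 3 Calvin cycle genes, 0.5 for the 8 tetrapyrrole synthesis genes, 0.17 for the 9 expansins and xyloglucan hydrolases and 0.54 for the 3 gibberellin genes, whose median (-0.23) and mean (0.01) differed in sign. EXPB1, an expansin, was the 1 member of these called over all genes and fell by 0.79 (adjusted p = 0.0048). Adjusted over the list alone, 3 expansins and xyloglucan hydrolases were lower, and of the gibberellin genes 1 was higher and 2 were lower. The 25S rRNA signal was low in all 3 WT_R1 arrays and, of the WT_D1 arrays, in replicate 2. With that signal as a covariate 620 probe sets were called, and 728 were called with only WT_R1 and WT_D1 in the fit. With no scaling between arrays 165 were called, 132 higher and 33 lower, which is 80% higher against 56.3% here, and FHL, HAT2, GH3.3, IAA20, EXPB1, LHCB4.2, LHCB4.3, PSBY and PSBW lost their call. The camera adjusted p of the antenna list was then 0.071. Its median log2 change was 0.35 against -0.07 for all named genes, where the main setting gave 0.42 and -0.02.

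After 18 h of red light the transcriptome had changed broadly, with photosynthesis and flavonoid genes higher and auxin response and shade genes lower than after 18 h more of darkness. RCA, the Rubisco activase, rose from 1377 ± 237 to 6618 ± 130 units (SD, n = 3 each) and SBPASE, a Calvin cycle phosphatase, by a log2 change of 2.82 (SE 0.21). PSAN of photosystem I rose by 2.19 (SE 0.11). PAP85, a vicilin-like storage protein gene, fell by 3.75 (SE 0.30) from 1909 ± 359 to 133.4 ± 57.4 units, and IAA20 fell from 236.1 units to near background, at 4.472. Of 22746 probe sets, 7828 were called, 3213 higher and 4615 lower. At least 2-fold changes were mostly upward, with 1214 higher and 596 lower.

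The largest increases at 18 h, with the offset used here, were AT5G59250 (log2 change 5.36), AT5G48490 (5.17), AT2G34620 (4.82), AT1G21500 (4.80), AT1G52510 (4.47), AT4G28780 (4.43), AT1G60590 (4.11) and THI2.2 (4.08). AT5G48490, a lipid transfer protein gene, went from 75.07 ± 16.5 to 3258 ± 487 units, and AT1G21500 from 66.27 ± 26.3 to 2200 ± 142. Of the 16 ranked genes, 9 had a group mean under the offset, so that the size and rank of their changes rest on it. Among the increases these were AT5G59250, THI2.2 and AT4G28780, with means below 0 in darkness, and AT1G60590 and AT1G52510, at 5.549 and 5.993 units. Over all settings tried their changes ran from 3.47 to 9.33 for AT5G59250, 2.32 to 8.0 for THI2.2, 2.62 to 8.37 for AT4G28780, 2.55 to 6.46 for AT1G60590 and 2.91 to 6.42 for AT1G52510, against 4.57 to 5.43 for AT5G48490. The largest decreases were AT3G05260 (-3.76), PAP85, AT2G34020 (-3.65), IAA20 (-3.54), AT5G02580 (-3.42), AT3G01570 (-3.31), M10 (-3.31) and AT4G11610 (-3.10). M10 encodes a late embryogenesis protein and AT3G01570 an oleosin, the protein of seed oil bodies. AT3G01570 went from 931.5 ± 195 to 81.53 ± 30 units. AT3G05260, M10, IAA20 and AT2G34020 had group means under the offset after red light, at -10.25, -24.78, 4.472 and 14.63 units. Their changes ran from -7.65 to -2.06, -7.15 to -1.70, -5.73 to -2.09 and -5.0 to -2.40 over all settings tried. The adjusted p of these 16 genes was at most 5.1e-07.

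The photosynthesis lists rose together at 18 h. All 3 measured antenna proteins (camera adjusted p = 8.8e-06), all 5 measured photosystem and electron transport subunits (4e-08) and all 3 measured Calvin cycle genes (2.9e-05) were called higher, with the same counts of 3, 5 and 3 adjusted over the list alone. LHCB4.3 rose by 1.53, LHCB4.2 by 1.33 and LHCB4.1 by 1.12. PSBY rose by 1.95, ATPC1, the gamma subunit of the chloroplast ATP synthase, by 1.56, and PRK by 1.22. In tetrapyrrole synthesis, the pathway to chlorophyll and heme, 6 of 8 genes were higher at either adjustment (adjusted p = 2e-05), and the adjusted p was 0.07 with an estimated correlation. CHLI2 rose by 2.40, HEME1 by 2.35, HEME2 by 2.13 and CHLM by 1.26. Flavonoid and phenylpropanoid genes rose as well (adjusted p = 8.8e-06), with 5 of 6 called higher over all genes and 5 adjusted over the list alone. UGT78D2 rose by 2.28, UGT78D1 by 2.09 and CHIL by 2.37. In darkness UGT78D1 was at 12.99 units and CHIL at -18.38, and their changes ran from 1.15 to 3.01 and from 1.04 to 6.07 over all settings tried.

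Shade and PIF target genes were lower at 18 h (adjusted p = 2.9e-05), 3 of 3 at either adjustment, with log2 changes of -1.91 for IAA29, -1.71 for FHL and -1.44 for HAT2. Auxin response genes were lower (7.4e-07), 7 of 8 over all genes and 7 adjusted over the list alone, with GH3.3 at -2.15. Without IAA29 and HAT2, which the lists share, 5 of 6 were lower and the adjusted p was 5.3e-05. Expansins and xyloglucan hydrolases went both ways (adjusted p = 0.5): 2 were higher, 4 were lower, and the same numbers were found adjusted over the list alone. EXPB3 rose by 2.59, while XTH19 fell by 1.44 and EXPA4 fell by 1.06. Of the gibberellin genes (adjusted p = 0.14), the receptors GID1A and GID1C fell by 0.45 and 0.43, 2 of 3 members at either adjustment. With no scaling between arrays 1997 probe sets were called and 75.8% of them were higher, against 41% here.

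**Figure D2:**
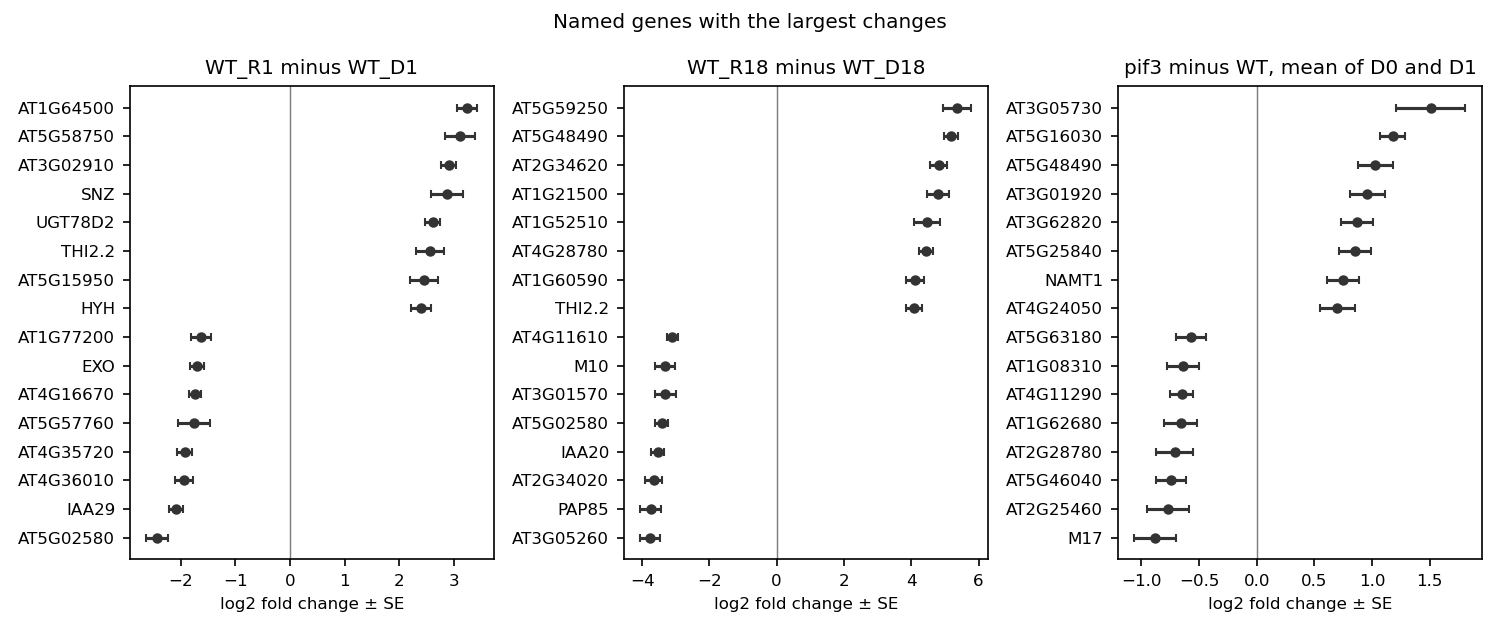
log2 fold change with its SE for the 16 named genes of each main comparison, from 3 arrays per group. With the offset used here, changes reach 5.36 at 18 h of red light, 3.24 at 1 h and 1.51 in pif3.

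The red light changes at 1 h and 18 h came from different arrays and were largely of 1 direction. Of the 526 named genes called at 1 h, 438 had the same sign at 18 h. Called at both times, 183 genes were higher and 171 lower, where independent lists would share 33.2 and 49.8. Opposite calls numbered 35, where independent lists would give 83.5. Across 13356 genes, which are not independent replicates, the changes correlated at r = 0.35. THI2.2 was 2.56 higher at 1 h and 4.08 at 18 h, and UGT78D2 was 2.61 and 2.28 higher. IAA29 changed by -2.09 and -1.91, and AT5G02580 by -2.43 and -3.42.

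The difference between the red light changes at the 2 times was called for 4265 probe sets, 2112 with a higher value at 18 h and 2153 with a lower one. Named genes with the largest differences upward were AT1G52510 (4.71), AT4G28780 (4.64), AT5G48490 (4.44), AT5G59250 (4.24) and AT1G21500 (4.23). Those downward were PAP85 (-3.64), AT3G05260 (-3.59), AT5G58750 (-3.36), M10 (-3.30) and AT2G34020 (-3.08). Of these 10, 7 had a group mean under the offset and their sizes rest on it. Over all settings tried they ran from 2.99 to 7.01 for AT1G52510, 2.68 to 9.45 for AT4G28780, 3.09 to 5.07 for AT5G59250, -7.46 to -1.94 for AT3G05260, -7.43 to -1.67 for AT5G58750, -7.14 to -1.69 for M10 and -4.4 to -1.88 for AT2G34020. The call of AT5G59250 was lost with an offset of 1 (adjusted p = 0.095). AT5G58750 was higher only at 1 h among these times, with a log2 change of -0.25 (adjusted p = 0.56) at 18 h. The antenna, photosystem and Calvin cycle lists were higher in the later change, with 3 of 3, 5 of 5 and 3 of 3 members called at either adjustment (camera adjusted p = 2.8e-05, 1.2e-07 and 6.4e-05). Tetrapyrrole synthesis (1.8e-05) had 6 of 8 members higher and 1 lower, with an adjusted p of 0.067 with an estimated correlation. The flavonoid list was higher (0.0026) with 3 of 6 members called and 4 adjusted over the list alone, and the auxin list was lower (0.00013) with 6 of 8 at either adjustment, and with 0.00012 and 5 of 6 without IAA29 and HAT2. Shade genes (0.058), gibberellin genes (0.22) and expansins and xyloglucan hydrolases (0.82, with a median of -0.37 and a mean of 0.03) were not called. With the 25S rRNA signal as a covariate 2172 probe sets were called, 60.3% of them higher against 49.5% here, and with no scaling 639, 87.5% of them higher. That signal was low in all WT_R1 arrays and high in all WT_R18 arrays, and its part in this difference was not tested further.

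In darkness the pif3 mutant differed from wild type by small changes. As the mean of D0 and D1, 406 of 22746 probe sets were called, 257 higher and 149 lower, and 9 changed at least 2-fold. AT5G16030 was 1.18 higher on the log2 scale (SE 0.11, adjusted p = 9.2e-05), at 526.1 ± 90.8 units in 6 pif3 arrays against 222.3 ± 27.3 in 6 wild-type arrays. LHCB4.2, a light-harvesting protein of photosystem II, was 0.44 higher (SE 0.05), at 2758 ± 155 against 2031 ± 110 units. M17, a late embryogenesis gene, had a log2 change of -0.88 (SE 0.18), at 167.3 ± 46 against 319.2 ± 65.9 units. PIF3 itself has no named probe set and was not analysed here, so these arrays rest on their labels.

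The 8 largest increases in pif3 were AT3G05730 (1.51), AT5G16030, AT5G48490 (1.03), AT3G01920 (0.96), AT3G62820 (0.87), AT5G25840 (0.85), NAMT1 (0.75) and AT4G24050 (0.70). The 8 largest decreases were M17, AT2G25460 (-0.77), AT5G46040 (-0.74), AT2G28780 (-0.71), AT1G62680 (-0.66), AT4G11290 (-0.65), AT1G08310 (-0.64) and AT5G63180 (-0.57). AT1G62680 and AT2G25460 had a group mean under the offset, at -2.797 units in pif3_D1 and 13.61 in pif3_D0, and their changes ran from -2.9 to -0.21 and from -1.29 to -0.36 over all settings tried. The adjusted p of the 16 genes lay between 9.2e-05 and 0.038. With any 1 array left out, AT5G16030, AT5G48490, AT3G01920, AT3G62820, AT5G25840, AT4G11290 and AT5G46040 remained called, with adjusted p up to 0.037 for AT5G46040. NAMT1 lost its call in 1 of these 12 fits, AT3G05730 in 4, M17 in 6, AT1G62680 in 7, AT2G28780, AT1G08310 and AT4G24050 in 8, AT2G25460 in 9 and AT5G63180 in 10. The genes that kept their call in all 12 fits each lost it in 1 of the other settings.

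Of the gene lists, the antenna proteins were higher in pif3 (camera adjusted p = 0.0023), with LHCB4.2 and LHCB4.1 (0.38) called and 2 of 3 adjusted over the list alone. The photosystem and electron transport subunits were higher (adjusted p = 7.8e-05), and the adjusted p was 0.096 with an estimated correlation. PSAN (0.31, adjusted p = 0.048) was the 1 of its 5 members called, and 4 were higher when adjusted over the list alone. PSAN lost its call with any 1 of the 12 arrays left out (adjusted p up to 0.12), while LHCB4.2 and LHCB4.1 lost theirs in 0 of these fits. The Calvin cycle list had an adjusted p of 0.044, which was 0.39 with an estimated correlation and 0.17 with only dark wild-type arrays of high 25S rRNA signal, and none of its 3 members was called at either adjustment. PRK was at 0.32 with an adjusted p of 0.22. No list of shade (0.96), auxin response (0.77), gibberellin (0.77), flavonoid (0.96), expansin (0.96) or tetrapyrrole (0.15) genes was called, and neither was any of their members over all genes. Adjusted over the list alone, 1 auxin response gene was higher, and 1 expansin or xyloglucan hydrolase gene was higher and 2 were lower. The shade list's median (-0.05) and mean (0.02) differed in sign. IAA29 was at 0.22 (adjusted p = 0.26).

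**Figure D3:**
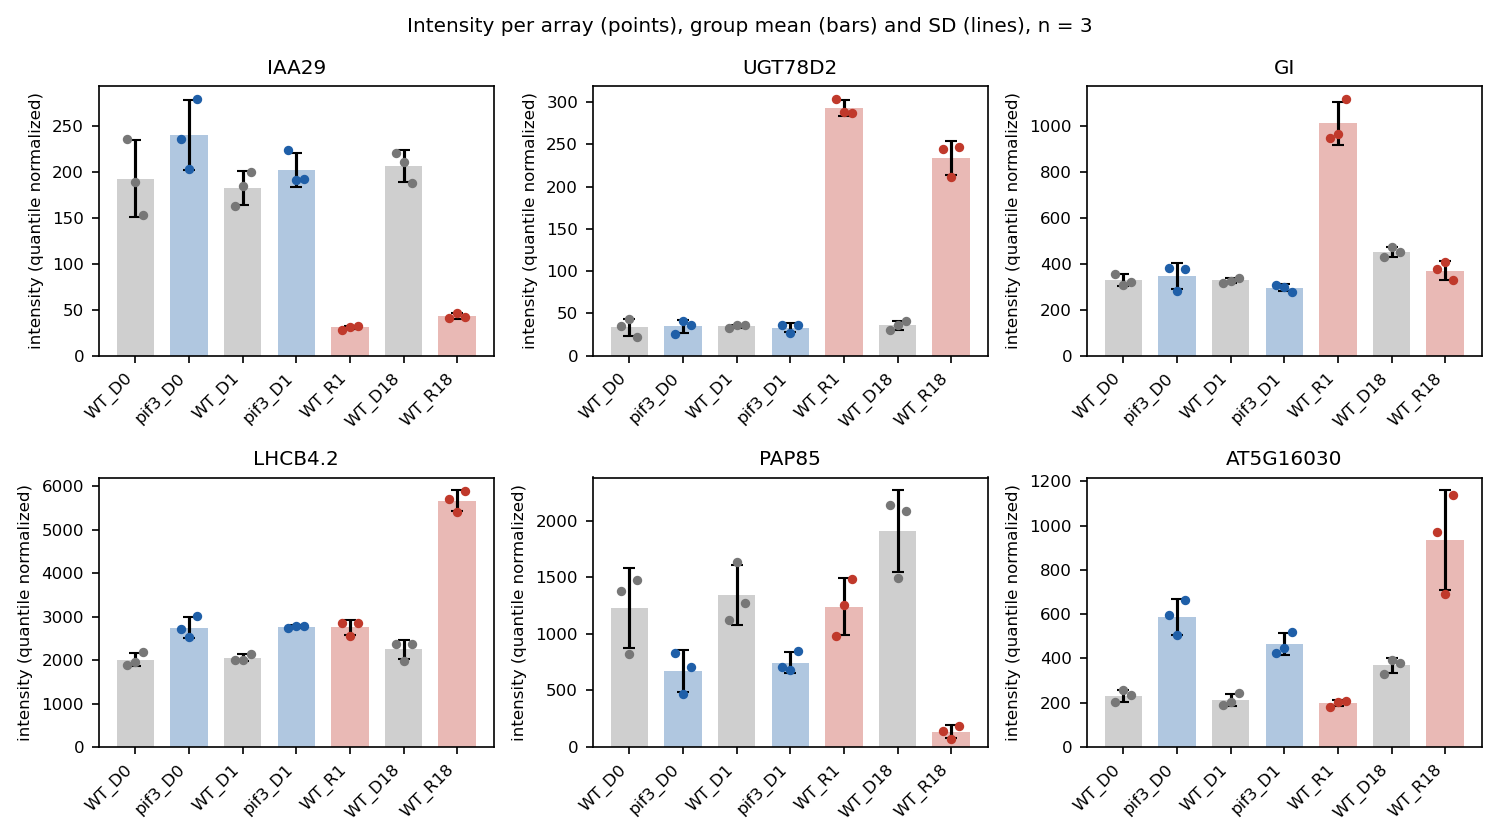
Quantile-normalized intensity of 6 named genes, with points for arrays, bars for group means and lines for the SD (n = 3). IAA29 and UGT78D2 separate red light from darkness, and GI is highest in WT_R1. LHCB4.2 is higher in WT_R1, WT_R18 and pif3 than in dark wild type.

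The pif3 count depended on single arrays and on the control arrays. It was 200 without pif3_D0 replicate 1, 185 without pif3_D0 replicate 3, 179 without pif3_D1 replicate 1, 183 without pif3_D1 replicate 3, 233 without WT_D0 replicate 1, 193 without WT_D1 replicate 1, 260 without WT_D1 replicate 2 and 223 without WT_D1 replicate 3. All pif3 arrays had a high 25S rRNA signal. Against only the 4 wild-type arrays with a high signal 116 probe sets were called, with the signal as a covariate 251, with only these groups in the fit 229 and with no scaling 4. Of these 4, 25% were higher, against 63.3% here.

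At each dark time alone the mutant showed fewer calls. At D0, 67 probe sets were called, 51 higher and 16 lower, and at D1 9 were called, 6 higher and 3 lower. With only dark wild-type arrays of high 25S rRNA signal the split was nearly even, with 39 called at D0, 19 higher and 20 lower, and 14 at D1, 7 higher and 7 lower. With each array scaled to a common median 109 were called at D0, 87.2% of them higher against 76.1% here, and with no scaling 1 at D0, which was lower, and 2 at D1, 1 higher and 1 lower. AT5G16030 was higher at both times, by 1.28 at D0 and 1.07 at D1. At D0 the other named increases were AT3G24460 (0.79), AT5G19940 (0.64), AT1G07440 (0.63) and the plastid gene atpA (0.61), and the decreases were AT4G11290 (-0.81), AT1G11740 (-0.78), AT5G49390 (-0.67), AT2G31730 (-0.61) and JAL33 (-0.52). AT3G24460 lay near background, at -7.651 units in WT_D0 and 12.03 in pif3_D0, and its change ran from 0.25 to 3.63 over all settings tried. AT5G49390 was at 16.33 units in pif3_D0 and ran from -1.06 to -0.31. With any 1 of the 6 arrays of D0 left out, AT5G16030 and AT3G24460 lost their call in 0 fits, AT1G07440 and AT5G49390 in 3, atpA, AT4G11290, AT2G31730 and JAL33 in 4, AT1G11740 in 5 and AT5G19940 in 6. At D1 the only other named gene called was TBL45 (-0.43), which lost its call in 5 of 6 fits with an array of D1 left out, while AT5G16030 lost its call in 3. The antenna proteins were higher at D1 (camera adjusted p = 0.00071) and at D0 (0.017, with an adjusted p of 0.14 with an estimated correlation), with 2 of 3 members adjusted over the list alone at each time. LHCB4.2 was called over all genes at D0 (0.45), but not in 4 of the 6 fits with an array left out, and had an adjusted p of 0.077 at D1 (0.43). The photosystem list had an adjusted p of 7.3e-05 at D1 and 0.013 at D0, and 0.094 and 0.38 with an estimated correlation. The Calvin cycle list had an adjusted p of 0.046 at D0, which was 0.39 with an estimated correlation, with 0 of 3 members called at either adjustment. With only dark wild-type arrays of high 25S rRNA signal the adjusted p at D0 was 0.072 for the antenna, 0.22 for the photosystem and 0.45 for the Calvin cycle list, and with no scaling 0.23, 0.19 and 0.13. Their medians with no scaling were 0.26, 0.05 and 0.11 against -0.15 for all named genes. In the main setting these were 0.4, 0.26 and 0.3 against 0. With only the 2 groups of each time in the fit, 0 probe sets were called at D0 and 2 at D1. The D0 count was 25 without pif3_D0 replicate 1, 258 without replicate 2 and 18 without replicate 3. The D1 count was 15 without pif3_D1 replicate 2, 2 without pif3_D1 replicate 3 and 5 without WT_D1 replicate 1.

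Single genes showed no detectable difference of the pif3 effect between D0 and D1. limma called 0 probe sets for the genotype by hour difference, 857 had an unadjusted p under 0.05, and camera called none of the 9 lists (adjusted p = 0.85 for each). Of the families, plastid-encoded photosystem, cytochrome, ATP synthase and rbcL genes (camera adjusted p = 3.5e-08), plastid-encoded NDH subunits (0.00083) and plastid-encoded ribosome and RNA polymerase genes (0.00059) had lower pif3 effects at D1 than at D0, and tau glutathione transferases (0.02) higher ones. With an estimated correlation the adjusted p was 0.82 for each plastid family and 0.22 for the last. Over that hour of darkness the median log2 changes of the 3 plastid families were 0.29, 0.23 and 0.48 in wild type and -0.12, 0.01 and 0.03 in pif3 (camera adjusted p = 0.33, 0.53 and 0.21 in pif3). The pif3 effect at D0, the wild-type changes in darkness and this difference all use the WT_D0 arrays. Their plastid family calls are therefore not independent, and a shift in WT_D0 alone would move all of them. No scaling moved the median of all named genes by 0.23 for the difference, and the plastid families stayed below that median. The adjusted p of the tau glutathione transferases was then 0.083, and 0.12 with only dark wild-type arrays of high 25S rRNA signal. AT5G16030 had a difference of -0.21 (SE 0.22). With only dark wild-type arrays of high 25S rRNA signal 6 probe sets were called. The count was 8 without pif3_D0 replicate 2, 4 without WT_D0 replicate 1, 2 without WT_D0 replicate 2 or pif3_D1 replicate 1 and 1 without pif3_D0 replicate 1, pif3_D1 replicate 3 or WT_D1 replicate 2.

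With all arrays, time in darkness gave few calls. limma called 0 probe sets between WT_D1 and WT_D0, with 1693 at an unadjusted p under 0.05. That count was 112 without WT_D0 replicate 1, an array with a low 25S rRNA signal, 1 without WT_D1 replicate 1 and 2 without WT_D1 replicate 2 or WT_D0 replicate 2. No list was called (camera adjusted p from 0.4 to 0.95). Of the families, 3 of plastid-encoded genes were higher with the preset correlation and 0 families were called with an estimated one. These were the photosystem, cytochrome and ATP synthase genes (median log2 change 0.29, camera adjusted p = 4.8e-08, and an adjusted p of 0.68 with an estimated correlation), the NDH subunits (0.23, 0.002, and 0.71) and the ribosome and RNA polymerase genes (0.48, 4.5e-12, and 0.37). They rest on the same WT_D0 arrays as the plastid family calls for genotype by hour. With only dark wild-type arrays of high 25S rRNA signal 80 probe sets were called at 1 h and 257 at 18 h. Between WT_D18 and WT_D0 it called 10, 4 higher and 6 lower, and the 4 named ones were all lower: NRPB9A (-0.92), AT2G02880 (-0.37), AT3G56480 (-0.29) and AT1G42960 (-0.25). NRPB9A was at 8.512 units in WT_D18 and ran from -1.71 to -0.38 over all settings tried. With any 1 of the 6 arrays left out, AT3G56480 lost its call in 4 fits and the other 3 in 5. The 18 h count rose to 570 without WT_D0 replicate 1, and was 4 without WT_D18 replicate 1, 2 without WT_D0 replicate 2 and 0 without WT_D0 replicate 3 or WT_D18 replicate 2 or 3. The gibberellin list was higher over the 18 h (camera adjusted p = 0.034), with an adjusted p of 0.1 with an estimated correlation and 0.14 with no scaling, and 0 of its 3 members called over all genes, against 2 adjusted over the list alone.

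In pif3, 1 h more of darkness gave 42 calls, 19 higher and 23 lower. Named increases were AT5G42060 (0.87), AT1G15120 (0.72), AT5G47060 (0.69), AT5G61310 (0.65) and AT1G63980 (0.58), and named decreases were AT1G15480 (-1.17), AT3G24460 (-0.79), AT1G34150 (-0.64), AT5G65820 (-0.47) and AT4G18870 (-0.47). Of these 10, 5 had a group mean under the offset: AT3G24460, AT5G65820, AT4G18870 and AT1G15480 in pif3_D1, at -11.27, -1.878, -3.133 and 3.861 units, and AT5G42060 in pif3_D0, at 13.07. Over all settings tried their changes ran from -3.63 to -0.25, -2.82 to -0.13, -2.57 to -0.13, -3.07 to -0.44 and 0.39 to 1.44. With any 1 of the 6 arrays left out, AT1G15480 and AT3G24460 lost their call in 4 fits, AT4G18870 in 6 and the other 7 in 5. The count was 10 without pif3_D1 replicate 1, 9 without pif3_D1 replicate 2 or pif3_D0 replicate 1, 1 without pif3_D1 replicate 3, 4 without pif3_D0 replicate 3 and 163 without pif3_D0 replicate 2. No list was called (camera adjusted p from 0.29 to 0.98). With only these groups in the fit the count was 0, with the low 25S rRNA wild-type arrays left out of the fit 109, and with each array scaled to a common median 188 were called, of which 20.2% were higher, against 45.2% here.

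For the mean of D0 and D1, pif3 and red 18 h shared more calls in the same direction than in opposite ones. The 2 comparisons share no array, but share 1 estimate of the spread per probe set, so their calls are not independent. Among 13356 named genes, 46 were called higher in both and 30 lower in both, where independent lists would share 15.8 and 14. Opposite calls numbered 51, where independent lists would give 33.5, and thus exceeded their number under independence as well. The genes higher in both included AT3G05730 (1.51 in pif3, 3.73 at 18 h), AT5G48490 (1.03 and 5.17), LHCB4.2 (0.44 and 1.33), PSAN (0.31 and 2.19), NdhS (0.39 and 1.11) and HPR (0.37 and 1.64). NdhS belongs to the chloroplast NDH complex and HPR is the photorespiratory hydroxypyruvate reductase. M17 was lower in both (-0.88 and -2.46), as was AT4G11290 (-0.65 and -0.79). Among the largest increases in pif3, NAMT1 (0.75 and -0.84) and AT4G24050 (0.7 and -0.74) were called the opposite way at 18 h. AT3G62820 (0.87 and -0.41) and AT3G01920 (0.96 and -0.13) had the other sign at 18 h without a call. So did AT1G62680 (-0.66 and 0.12) and AT5G63180 (-0.57 and 0.45) among the largest decreases. NdhS and HPR lie outside the rule and were chosen after their values were seen. Across genes the changes correlated at r = 0.17, and 114 of the 200 named genes called in pif3 had the same sign at 18 h. The correlation with red 18 h was 0.12 for the pif3 effect at D0 and 0.15 for that at D1, and the covariance was 0.0163 for the mean, 0.0161 at D0 and 0.0165 at D1. Among called genes the pif3 effect at D0 alone showed no such agreement: 5 were higher in both, 2 lower in both and 10 opposite, where independent lists would give 2.24, 1.73 and 4.58, and 10 of 27 had the same sign. With the dark wild-type arrays of high 25S rRNA signal alone, 14 genes were shared in direction, against 76 here, and with no scaling 0.

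The pif3 and red 1 h comparisons share the WT_D1 arrays. Called in both, 8 genes were higher, 9 lower and 8 opposite, where independent lists would share 2.54, 1.42 and 3.92. The correlation across genes was 0.11 and the covariance 0.00527, against 0.35 and 0.00872 in simulated groups with no effect that share these controls. Both lay below the simulated values, so neither shows agreement beyond what the shared arrays give. Part or all of the shared calls may therefore come from the shared arrays, which are too few to split. The pif3 effect at D0, which shares no array with red 1 h, correlated with it at r = -0.06.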

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

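The tests of the differences below were set before the data were examined, and the count of opposite changes was chosen after the calls had been seen. The red light changes at 18 h and at 1 h differed for 4265 probe sets by a test of the difference itself. Of 100 ways to exchange the times within red light and within darkness, 1, the real one, gave as many, and the highest of the others gave 3222. That is the lowest share that 100 ways can give, and it makes chance assignment of the times unlikely. Many of the other ways keep part of the real arrangement.

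Named genes called in opposite directions at the 2 times, with the difference itself called, numbered 35. Independent lists would give 83.5 opposite calls, so opposite changes were fewer than under independence. Of the 35 genes, 12 were higher at 1 h and lower at 18 h, and 23 the other way. GI, which acts in the circadian clock, was 1.58 higher (SE 0.10) at 1 h and had a log2 change of -0.28 (SE 0.10, adjusted p = 0.047) at 18 h. Against the dark seedlings before the light the 18 h value of GI was 0.16, and with any 1 of the 6 arrays left out its call at 18 h was lost in 5 fits. AT1G73480 was at 2.04 and -0.46, AT3G51660 at 1.02 and -1.01, and AT5G33370 at 0.77 and -0.91. AT3G15570 was at -1.26 and 0.83, AT3G53250 at -0.88 and 1.03, AT5G44680 at -0.67 and 1.22, and XTH16, a xyloglucan endotransglucosylase, at -0.55 and 0.80. AT3G15570 was at -13.67 units in WT_R1 and AT5G33370 at -2.23 in WT_R18, so that the sizes of their changes rest on the offset. Apart from GI and XTH16 these genes were taken as examples after their values were seen.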

How the results depend on the processing

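Median scaling was planned, and the unscaled values, the offsets outside red 1 h and the 25S rRNA settings were chosen after the data were seen. Quantile normalization, planned as an alternative, became the main setting. The cause of the moves below was not tested except where fewer probe sets or arrays were used. Dim probe sets lie near the offset, where changes are understated. No scaling called 165 probe sets at red 1 h (80% higher), 1997 at red 18 h, 1 for pif3 at D0, 2 at D1, 4 for the pif3 mean (25% higher), 0 for dark 18 h, 0 for dark 1 h in pif3, 639 for red 18 h against red 1 h (87.5% higher) and 0 for the overlap. It moved the median of all probe sets by -0.16 for pif3 at D0, 0.14 for dark 1 h, 0.39 for dark 1 h in pif3 and 0.24 for genotype by hour. ALDH10A9 in pif3 at 1 h of darkness turned to 0.06. Median scaling called 109 for pif3 at D0 (87.2% higher against 76.1%) and 188 for dark 1 h in pif3. With the dimmest probe sets left out dark 18 h had 3 calls and dark 1 h in pif3 0. A variance trend gave 1 for genotype by hour. Offset 1 gave 4 for dark 1 h and 6 for dark 18 h. With 1 probe set per named gene, fewer tests gave 483, 4141, 6, 0, 157, 0, 10 and 2103 calls for red 1 h, red 18 h, pif3 at D0, at D1, their mean, dark 18 h, dark 1 h in pif3 and red 18 h against red 1 h. With only the compared groups in the fit these were 728 for red 1 h, 0 and 2 for pif3 at D0 and D1, 229 for their mean, 0 for dark 18 h and 0 for dark 1 h in pif3. The 25S rRNA covariate gave 620 for red 1 h, 5 for pif3 at D1, 251 for the pif3 mean, 0 for dark 18 h and 2172 for red 18 h against red 1 h. Dark wild-type arrays of high 25S rRNA signal alone gave 39 for pif3 at D0, 14 at D1, 116 for their mean, 80 for dark 1 h, 257 for dark 18 h, 109 for dark 1 h in pif3, 6 for genotype by hour and 14 for the overlap, and the low WT_D1 array alone gave 515 for red 1 h. The overlap was 3 with a 2-fold change asked for. An estimated correlation left 1 of 3 lists called for the pif3 mean. Against dark seedlings before the light, the 18 h values turned for GI (0.16), BGLU25 (-0.16), CRR28 (0), RALFL34 (-0.02) and SBT4.12 (-0.16). Leaving out each array gave 861 to 1006 calls for red 1 h, 6568 to 7328 for red 18 h, 18 to 258 for pif3 at D0, 2 to 15 at D1, 179 to 559 for the pif3 mean, 0 to 112 for dark 1 h, 0 to 570 for dark 18 h, 1 to 163 for dark 1 h in pif3, 0 to 8 for genotype by hour and 3530 to 4518 for red 18 h against red 1 h. Where this left 2 arrays in a group, the spread was pooled over groups. Of 6192 values of named genes in these fits, 505 lost their call and 42 gained one. The red 1 h and red 18 h counts stayed within 1.5 times under median scaling, the variance trend, both offsets, the filter and each omitted array.

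The replicate numbers are shared by the groups. In 1 of 21 group pairs, WT_D18 and WT_R1 (r = 0.32, 0.48 and 0.13), all same-numbered residuals correlated above 0.1. Over all pairs these correlations ran from -0.25 to 0.48, so the numbers did not pair the arrays in general. With the replicate block the calls were 1125 for red 1 h, 7838 for red 18 h, 77 for pif3 at D0, 8 at D1, 474 for their mean, 0 for dark 1 h, 2 for dark 18 h, 53 for dark 1 h in pif3, 0 for genotype by hour and 4283 for red 18 h against red 1 h.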

Other observations

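The choice of the seed-stage genes, the tests of families under other scalings and with arrays of high 25S rRNA signal, and the auxin list without shared members came after related values had been seen. So did the tests of sample preparation for the red 1 h and pif3 calls. Single seed-stage genes had lower values after 18 h of red light, without a set test that carries them. In the late embryogenesis family 4 of 5 members were lower and 1 higher, with a camera adjusted p of 0.27 and 0.42 with an estimated correlation. That family does not hold PAP85, AT3G01570 or OLEO3, nor every late embryogenesis gene named here. Its test therefore does not speak for all of these genes. OLEO3, an oleosin, had a log2 change of -2.53 (SE 0.14, adjusted p = 2.1e-09), and the late embryogenesis genes AT2G42560, LEA18, LEA4-5 and AtLEA4-1 had -2.52, -1.42, -1.03 and -0.85, and AT2G46140 had -0.62, beside PAP85, AT3G01570, M10 and M17. The mean of AT2G42560 after red light was 0.6512 units, so that the size of its change rests on the offset. AT2G44060, named in the same family, was higher by 0.29. Over the same 18 h in darkness PAP85 was at 0.66 (adjusted p = 0.36) and OLEO3 at -0.32 (0.34). In dark pif3 only M17 of these was called, and PAP85 was at -0.84 (adjusted p = 0.06) and OLEO3 at -0.34 (0.1). LEA4-5 and AtLEA4-1 had adjusted p of 0.0096 and 0.047 at 18 h, and with any 1 of the 6 arrays left out they lost their call in 1 and 4 fits.

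Among the families, which share members with the fixed lists, some moved. Of the nuclear thylakoid family, LHCB4.1, LHCB4.2, LHCB4.3, PSBW and PSBY also belong to the antenna and photosystem lists. Nuclear thylakoid and photosystem proteins were higher at 1 h (5 of 15 called, camera adjusted p = 0.00017, and an adjusted p of 0.31 with an estimated correlation) and at 18 h (13 of 15, 2.1e-12, and 0.032), with TROL at 2.58, TAPX at 2.27 and AT1G52220 at 2.11 at 18 h. Tau glutathione transferases were higher at 1 h (0.00017, and 0.013 with an estimated correlation), with GSTU16 at 0.85 and GSTU18 at 0.53, 2 of 11 members called, and UDP-glycosyltransferases were higher with the preset correlation (0.012, and 0.22), with 4 of 47 members higher and 1 lower. At 18 h tubulins (5 of 7 lower), ATG autophagy genes (6 of 8 lower) and aldehyde dehydrogenases (6 of 8 lower) were called with the preset correlation, with adjusted p of 0.3, 0.38 and 0.21 with an estimated correlation and 0.07, 0.087 and 0.071 with no scaling. Their median log2 changes were -0.39, -0.4 and -0.47 with no scaling and -0.42, -0.42 and -0.5 in the main setting. Plastid-encoded photosystem, cytochrome and ATP synthase genes (8 of 33 higher and 2 lower) had 0.04, and 0.64 with an estimated correlation, 0.089 with median scaling and 0.052 with no scaling. TUB1 fell by 1.98, ATG8B fell by 1.18 and ALDH10A8 fell by 0.95. SPCH and FMA, of the fixed list of stomatal genes that was too small to test, were at 1.47 (adjusted p = 0.0033) and 0.59 (0.013) at 18 h, and the mean of SPCH in darkness lay below 0 units, its change running from 0.58 to 4.08 over all settings tried.

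In the other comparisons families were called with the preset correlation, and none of them with an estimated one. For the pif3 mean these were 7 of 34, with adjusted p from 0.23 to 0.65 with an estimated correlation. Higher were the plastid-encoded photosystem, cytochrome and ATP synthase genes (camera adjusted p = 2.3e-06), nuclear thylakoid and photosystem proteins (0.00035), Aux/IAA genes (0.0045) and plastid-encoded NDH subunits (0.02), and lower were tubulins (0.02), GH3 genes (0.024) and trichome birefringence-like genes (0.024). Of all their members, 2 thylakoid genes were called higher and 3 trichome birefringence-like genes lower. At D0 there were 5, with plastid-encoded photosystem (5.9e-11), NDH (0.00033), Aux/IAA (0.016) and nuclear thylakoid genes (0.016) higher and trichome birefringence-like genes (0.011) lower, and adjusted p from 0.28 to 0.47 with an estimated correlation. At D1 there were 3, with nuclear thylakoid (0.00021) and Aux/IAA genes (0.049) higher and tubulins (0.017) lower, each with an adjusted p of 0.28 with an estimated correlation. With only dark wild-type arrays of high 25S rRNA signal, 4 of the 7, 4 of the 5 and 3 of the 3 remained called, and with no scaling 4, 2 and 1. Over 18 h of darkness 5 families were called, with plastid-encoded NDH (0.0092), ribosome and polymerase (0.0092) and photosystem genes (0.016) and ATG genes (0.027) higher and aldehyde dehydrogenases (0.047) lower, and 1 of these, the ATG genes, remained called with the arrays of high signal. Their adjusted p with an estimated correlation ran from 0.59 to 0.68. The plastid-encoded calls at D0, for the pif3 mean and over darkness in wild type share the WT_D0 arrays and are not independent. Over 1 h of darkness in pif3 histones (0.026) and ATG genes (0.048) were higher (0.56 for each with an estimated correlation), and neither was called with no scaling. In the difference of the red light changes, nuclear thylakoid proteins (1.5e-10) and plastid-encoded photosystem genes (0.029) were higher and aldehyde dehydrogenases (0.0086) and ATG genes (0.029) lower, with 0.06, 0.69, 0.11 and 0.64 with an estimated correlation. With no scaling the aldehyde dehydrogenases (0.21) and ATG genes (0.25) were not called, and with median scaling the plastid-encoded photosystem genes (0.062) were not. No family turned its direction under another scaling. With the arrays of high signal none turned either, but the plastid-encoded photosystem genes over 18 h of darkness had a median of 0 (adjusted p = 0.95), which gives no direction.

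The 25S rRNA signal may mark a difference in how the samples were prepared for the arrays, called sample preparation here. It was low in all WT_R1 arrays and high in all WT_R18 and pif3 arrays. Dark wild type was mixed, and some of its arrays lay within the pif3 range. For red 1 h, 936 probe sets were called in a fit without the dark wild-type arrays of low signal. In each dark group the left-out array minus those of high signal moved these probe sets, in the direction of the red change, by a median of -0.02 (MAD 0.26) in WT_D0, 0 (MAD 0.16) in WT_D18 and 0.07 (MAD 0.18) in WT_D1, against a median red change of 0.77. The larger of the medians in WT_D0 and WT_D18 was 0 of the red change. An earlier form of the test, whose probe sets were called with those arrays in the fit, gave -0.0076. The value of 0 argues against sample preparation marked by this signal as the whole cause of the set. Each group has 1 such array, and the signal in WT_R1 was lower in part. Of the 1124 calls, 824 were shared with the fit without those arrays and 560 with the fit that had the signal as a covariate, and for the others this cause stays open. A response of the signal to the light itself was not tested.

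For the pif3 calls the same cause stays open. The 406 probe sets ranked first against wild-type arrays of low signal kept 0.491 of their change against those of high signal, and those ranked first against arrays of high signal kept 0.784 against those of low signal. The ratio of the shares was 0.626, between the bounds set for and against sample preparation. Fewer wild-type arrays had a low signal, so that ranking holds more noise. The first share can therefore be the lower one without any effect of sample preparation. An earlier form of the test was replaced because its probe sets were called with the tested arrays in the fit. It gave a median change of 0.36 against arrays of high signal and 0.40 against those of low signal. The ratio of 0.894 lay on the side against sample preparation. Of the 406 calls, 97 were shared with the fit without arrays of low signal and 219 with the fit that had the signal as a covariate. A biological effect of the mutation stays open as well, since the PIF3 transcript was not analysed.

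The pif3 and red 18 h changes went together across genes. With only arrays of a high 25S rRNA signal the correlation was 0.1 in place of 0.17. The ratio of 0.611 lies between the bounds set for and against sample preparation. Fewer arrays add noise, which lowers a correlation by itself, and the covariance was not taken there. The ratio therefore cannot weigh sample preparation. Sample preparation and a biological shift cannot be told apart for this overlap with these arrays. A partial shift of dark pif3 seedlings towards the state of red light was not tested apart from the values that raised it.

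Other splits of the arrays bear on the counts. For the pif3 mean, 1 of 100 exchanges of genotype within each time, the real one, gave 406 calls and the highest other gave 31. That is the lowest share that 100 exchanges can give, and it makes chance assignment of the genotypes unlikely for this count. For the genotype by hour difference the real count was 0, which all 100 exchanges reach, so that this comparison decides nothing. The highest count, 638, came when the times of the 4 wild-type arrays of high 25S rRNA signal were exchanged and those of the arrays of low signal were not. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 1124 and 4 for red 1 h, 7828 and 1 for red 18 h, 67 and 48 for pif3 at D0, 9 and 1 for pif3 at D1, 10 and 2 for dark 18 h, and 42 and 2 for dark 1 h in pif3. In each of these 1 of the 10 splits, the real one, reached the count. For dark 1 h the real count was 0, all 10 splits reached it and the highest other gave 7.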
